A study of Arabidopsis thaliana with 6 samples.

How the data were processed

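Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on whole Arabidopsis thaliana seedlings, 9 days old and grown in continuous white light, per the labels. The labels' protocols state that 2 g of seedlings were cross-linked for 20 min in 1% formaldehyde under vacuum, that chromatin was sonicated to 200 to 500 bp, and that antibody-bound protein A/G beads were used. The antibody label names HA, the epitope tag. The 6 libraries fall into 3 immunoprecipitated (IP) and 3 input libraries, grouped here by their descriptions, which read WDR5A-HA_pkl-IP and WDR5A-HA_pkl-input with replicate numbers. The genotype label of all 6 is WDR5A-HA_pkl. The titles of the same libraries read PKL_WT for the IP group and PKL_jaw-5D for the input group. They name PKL and not WDR5A, and other genotypes than the descriptions and the genotype label, so both bait and genotype rest on the descriptions, which were followed. Replicates are biological per the series' design text.

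The files analysed here are 3 summit lists, assigned to the 3 IP libraries. Input libraries had no list among the files analysed here, and no second genotype was analysed here, so no difference between groups could be computed. Each list gives the chromosome, a 1 bp summit position, a peak name and a strength. The strength is the −log10 q of the peak as deposited, a reading taken from the peak caller named in the notes and from the values, whose minimum sits at the −log10 of 0.05 (1.301). Per the submitters' processing notes, fastp, Bowtie2 2.3.3, MACS2 2.2.5 and deepTools were used, with the TAIR10 build. The peak thresholds, any use of the inputs as controls, and any filter on reads are not given in the sources used here. Each list carries its own replicate's peak names, so peaks were taken to be called per sample and not on pooled reads. Peak widths, fold enrichment, read numbers and depth were not used here. Because −log10 q grows with depth as well as with enrichment, it was used to rank summits within a list and as a descriptive mean over the lists, not to compare libraries in size. The depth of each sample is unknown, so no counting interval or detection limit is given, and a gene with no summit is a gene at which none was called.

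Positions were read as 1-based TAIR10 coordinates. Gene positions, classes and symbols came from an NCBI RefSeq gene table of assembly TAIR10.1, which holds 37899 genes on the 5 nuclear chromosomes, 27444 of them protein-coding. Because the assembly name differs from that in the notes, the match was checked on the data: over 26 blocks of 5 Mb, the share of regions within 250 bp of a protein-coding gene edge was highest with no shift in 26 blocks. Shifts of 500 to 5000 bp to either side were tried, and smaller ones were not. None of the table's coordinates is printed here. The table carries no strand, exon or UTR, and no genome sequence was used here, so gene starts and ends were not separated, exons, introns and UTRs were not assigned, and the sequence motif and exon number comparisons set before the data were examined were not run.

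Summits of different lists were linked when they lay within 250 bp, and a linked group holding a summit of each of the 3 lists was called a reproducible region, placed at its median summit. This replaced an overlap of at least 1 bp, since the files give no peak width. A gene was called a target gene when its window, the gene plus 500 bp to either side, held a summit in each of the 3 lists. The window set before the data were examined had only the upstream side, which needs strand. A summit in the windows of neighbouring genes counts for each of them. In an alternative, each summit was given to 1 gene, the gene it lies in or else the nearest within 500 bp. There a summit inside overlapping genes still counts for each of them. Centromeres were replaced by the 3 Mb window with the fewest protein-coding genes on each chromosome.

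Overlap between lists, genomic features and edge distances were tested against 1000 random placements within each chromosome (permutation tests, 1-sided for overlap and 2-sided otherwise, with 0.001 and 0.002 as the smallest p they can give). Gene lists and families were tested 2-sided against 10000 random lists matched on gene length decile (permutation test, smallest p 0.0002), with Benjamini-Hochberg adjustment over the 17 lists and, apart, over the 12 families with at least 5 members. Lists and family patterns were fixed before the data were examined, and 279 of the 279 listed genes matched the table. The NLR family pattern matched no gene of the table, which holds no product descriptions, and was left out. Families hold only genes whose symbol or synonyms carry the pattern, and patterns take in some unrelated genes: resistance genes (ribosomal), cyclophilins (P450), translation release factors (ERF/AP2) and HSPRO2 (heat shock). Narrower definitions added later gave ratios of 2.40 over 48 ribosomal, 0.696 over 241 P450 and 3.54 over 27 ERF/AP2 genes, each past the threshold, and 1.32 over 35 heat shock genes, not past it. Gene length and distance to the nearest protein-coding gene were compared with 100000 label permutations (smallest p 1e-05). Because a longer gene has a larger window, an alternative added later compared both with 1000 random placements of the reproducible regions, and both results are reported. Adjacent pairs of target genes were tested 1-sided against 1000 permutations within chromosome and length decile. Genes and regions are not independent replicates, and these p-values describe the arrangement of summits in these 3 lists.

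The genes named were fixed by rule: the 25 target genes with the highest mean strength, up to 4 targets of each list by that mean, list members with no summit in any list (not all of them are named), and WDR5A, PKL, FLC and the class of TCP factors related to CINCINNATA. The 10 widest regions of that rule could not be taken without widths. Members of families are given as examples chosen after their values were seen. On simulated data, 6000 of 6000 planted regions were recovered. Each was planted in all 3 lists with a jitter well below the linking distance. Their recovery was thus nearly fixed in advance and does not cover sites missed in a list. Of 20 planted lists of 20 genes set at 60% target genes, 19 were called, and 15 of 500 random lists (3%) were called. Alternatives changed the linking distance, the gene window, the strength required, the number of lists required, the random placement and the assignment of summits, and left out each replicate in turn. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.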

Results

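The libraries examined were described as seedlings carrying HA-tagged WDR5A in a pkl background. WDR5A is a WD40-repeat subunit of the COMPASS-like complexes that methylate lysine 4 of histone H3 (H3K4), and PKL (PICKLE) is a CHD3-type chromatin remodeller. The series title places the work in the regulation of H3K4 methylation by PKL and in the clustering of loci in the nucleus. The question open to the 3 IP summit lists was where tagged WDR5A was called in these seedlings. The lists held 10864, 10408 and 10826 summits for replicates 1, 2 and 3, a mean of 10699 ± 253 (SD, n = 3), all on the 5 nuclear chromosomes. Median strength was 7.08, 6.48 and 6.64 in −log10 q, and the highest summits reached 131.8, 97.6 and 117.8. The 3 input libraries enter no count, and the number of reads behind any summit is unknown.

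By mean strength over the 3 lists, the strongest summits fell in or next to the polyubiquitin gene UBQ10, the nitrate reductase gene NIA2, the BTB/TAZ scaffold gene BT2, the TOPLESS-related corepressor gene TPR3, AT5G21940 and the AP2/ERF-type regulator RAP2.4. The highest summit of replicate 1 (131.8) lay inside AT5G21940, that of replicate 2 (97.6) inside NIA2 and that of replicate 3 (117.8) next to TPR3. At UBQ10 (AT4G05320) the summit lay inside the gene at position 2720032 of chromosome 4 (TAIR10), with a mean −log10 q of 113 ± 16.5 (SD, n = 3). NIA2 (AT1G37130) reached 109.6 ± 17.6 (SD, n = 3) inside the gene at position 14160809 of chromosome 1, and BT2 (AT3G48360) reached 105 ± 12.8 (SD, n = 3) inside the gene at position 17909073 of chromosome 3. The TPR3 (AT5G27030) summit lay 149 bp outside the gene, at position 9515714 of chromosome 5, with 103 ± 13.5 (SD, n = 3), and the RAP2.4 (AT1G78080) summit lay inside its gene with 97.1 ± 15.1 (SD, n = 3). A further TOPLESS-related gene, TPR1, was also among the 25 strongest, at 69.6 ± 11.1 (SD, n = 3).

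Of the other genes among the 25, RBCS1A, a gene for the Rubisco small subunit, had a mean of 88.0 ± 4.41 (SD, n = 3), the ethylene response repressor ERF4 84.6 ± 9.19, the dehydration-response gene ERD15 84.3 ± 16.8, HSPRO2 84.0 ± 18.3 and the deadenylase gene CAF1a 78.6 ± 8.33. LBD41, a LOB-domain gene, stood at 72.2 ± 4.68, ADT5, an arogenate dehydratase gene, at 68.6 ± 2.48, the myo-inositol phosphate synthase gene MIPS1 at 67.9 ± 8.67 and the auxin receptor gene TIR1 at 67.7 ± 14.2. Genes known here only by locus were AT5G21940 (102.2 ± 26.4), AT4G32020 (87.8 ± 18.3), AT5G25280 (72.0 ± 16.5), AT5G54940 (69.1 ± 8.57), AT1G04000 (68.7 ± 2.97) and AT3G56360 (68.6 ± 5.14). AT5G07580 and AT5G07590 shared a summit at 70.0 ± 12.7, inside AT5G07590 and 461 bp outside AT5G07580. In the same way AGD13 was counted through the UBQ10 summit, 461 bp outside AGD13, and PAA2 through the AT5G21940 summit, 409 bp outside PAA2. The strongest region lay inside the gene for 15 of the 25 and outside it for 7. At RBCS1A, AT4G32020 and ERF4 the strongest summits of replicates 1 and 2 lay within 250 bp of each other. That of replicate 3 lay more than 250 bp from both. At ERF4 the strongest summits of replicates 1, 2 and 3 stood at positions 5121772, 5121830 and 5122749 of chromosome 3.

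**Figure D1:**
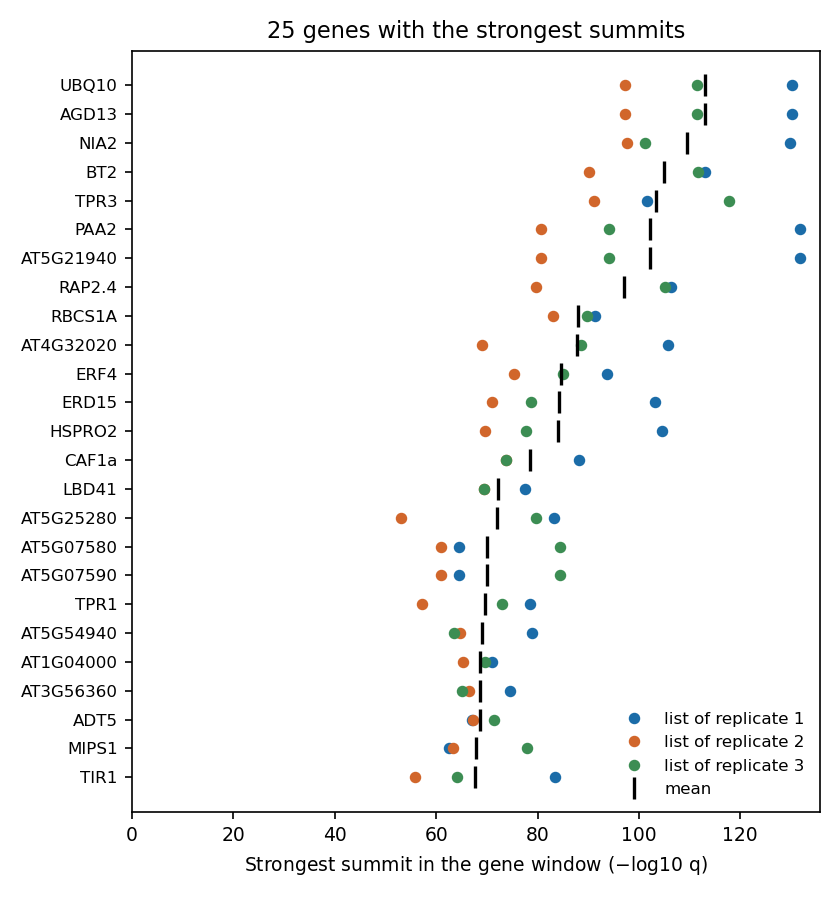
Strength of the strongest summit in the window of each of the 25 target genes with the highest mean, in −log10 q on a linear axis, with a point for the list of each replicate and a black tick for the mean. UBQ10 and AGD13, which share a summit, stand highest at 113, and TIR1 stands at 67.7.

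The same places were called in all 3 lists for the strong summits and for far fewer of the weak ones. Linking gave 15390 regions, of which 6684 (43.4%) held a summit of all 3 lists, 3325 (21.6%) of 2 lists and 5381 (35.0%) of 1 list. Random placement gave a mean of 30.4 regions in all 3 lists (permutation p = 0.001, 1-sided, the smallest 1000 placements can give). Of the summits of a list, 61.3% ± 1.59 (SD, n = 3) had a partner within 250 bp in both other lists and 16.7% ± 1.12 (SD, n = 3) had none. In the strongest decile 93.2% ± 0.662 (SD, n = 3) had a partner in both other lists, in the weakest 25.2% ± 1.65 (SD, n = 3). Within reproducible regions the summits spread over a median of 57 bp. Across these regions, which are not replicates, the strengths of pairs of lists had Spearman coefficients from 0.740 to 0.760 and Pearson coefficients on the log10 scale from 0.758 to 0.773. Among summits at or above the median strength of their list, 3267 regions were shared by all 3 lists.

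**Figure D2:**
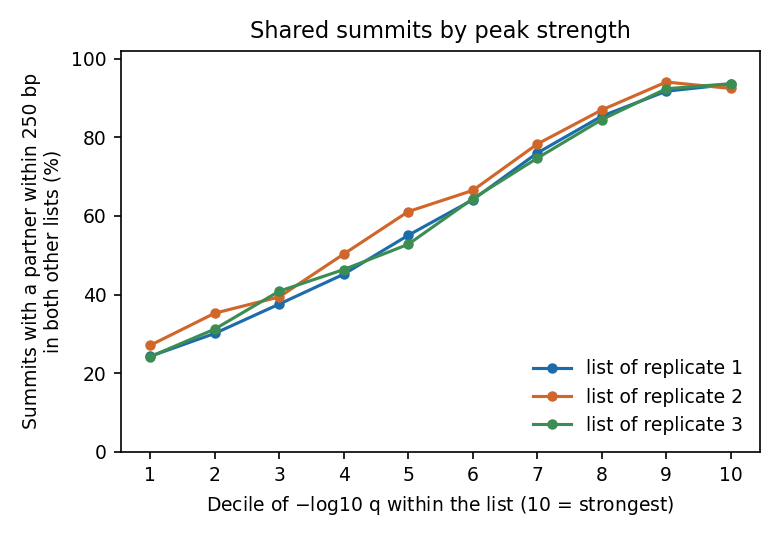
Share of summits, in percent, with a partner within 250 bp in both other lists, by decile of −log10 q within each list (10 is the strongest), with a line for the list of each replicate. The mean share is 25.2% in the weakest decile and 93.2% in the strongest.

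Reproducible regions gathered at the edges of protein-coding genes and at non-coding RNA genes, and were rare in pseudogenes. Of the 6684 regions, 67.8% lay within 500 bp of a protein-coding gene edge, against 35.4% of random positions, and 52.0% lay within 250 bp, against 19.6% (permutation p = 0.002 each, 2-sided, the smallest possible). The first 100 bp outside genes held 843 regions where random placement gave 238.4, 3.54 times as many, and the first 100 bp inside held 910 where it gave 326.6. Regions inside protein-coding genes made up 47.7% against 54.3% of random positions, and those in the 500 bp flanks 28.1% against 12.6%. Non-coding RNA genes held 4.65% against 1.35%, and pseudogenes, a class that in this table includes transposon-derived loci, held 26 regions, 0.389% against 8.60%. Other intergenic sequence held 19.2% against 23.2% (permutation p = 0.002 for each of the 5 classes, 2-sided). With random placement restricted to gene windows, the edge ratios were smaller, 67.8% against 52.5% within 500 bp (1.29 times, down from 1.92) and 52.0% against 29.0% within 250 bp (1.79 times, down from 2.65, permutation p = 0.002 for each). In that placement 80.3% of random positions lay in protein-coding genes and 0.587% in non-coding RNA genes. The ratios of observed to random were then 0.593 and 7.93 (permutation p = 0.002 for each). That placement puts every region in a gene window, while 1285 of the observed regions lay in other intergenic sequence. It therefore lowers the ratio inside protein-coding genes and the edge ratios in part by construction. It also leaves little non-coding RNA gene sequence, which raises the non-coding RNA ratio. Among summits at or above their list's median strength, other intergenic sequence was no longer below random placement over whole chromosomes, at 24.1% against 23.2% (permutation p = 0.278).

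Intergenic regions were among the strong ones. The median −log10 q was 11.6, 10.4 and 11.04 in other intergenic sequence for replicates 1, 2 and 3. It was 10.1 ± 0.350 (SD of the 3 lists' medians, n = 3) in non-coding RNA genes, 9.44 ± 0.765 in flanks of protein-coding genes, 8.23 ± 0.621 inside protein-coding genes and 6.41 ± 0.747 in pseudogenes. The classes stood in this order in each list, and the medians were not tested against each other. Strand was not used here, so the edges combine gene starts and gene ends.

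**Figure D3:**
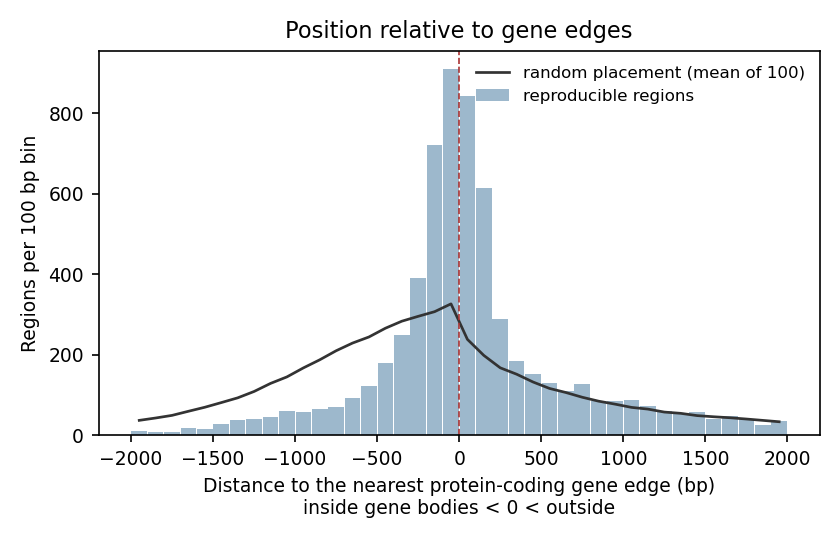
Number of reproducible regions per 100 bp bin (bars) and the mean of 100 random placements (line) by distance in bp from the nearest protein-coding gene edge, with positions inside genes below 0 and outside above 0. The bins next to the edge hold 910 regions inside and 843 outside, against 326.6 and 238.4 for random placement.

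Of 27444 protein-coding genes, 6801 (24.8%) were target genes, with a summit in their window in all 3 lists. Of these, 603 held no reproducible region in their window, RBCS1A, RCA, ZAR1 and WRKY33 among them. Their mean strengths do not describe 1 shared site in the window. A summit in 2 lists was found at 2388 genes, in 1 list at 2779 and in none at 15476. Single lists reached 9407, 9123 and 9428 genes, a mean of 9319 ± 170.4 (SD, n = 3). Target genes had a median length of 2422 bp against 1954 bp for the others, but longer genes have larger windows. For the 6281 genes with a reproducible region in their window the difference was 453 bp, below the 588.4 bp that random placement of the regions gave (permutation p = 0.002, 2-sided, the smallest possible). By length decile, 7.54% of the shortest and 31.5% of the longest genes held a region, against 8.06% and 31.9% with random placement over whole chromosomes. Every decile between lay above that placement, such as the fifth with 24.4% against 15.2%. With placement over gene windows only, the fifth stood against 21.6%, and the second, eighth and ninth lay below random. The shortest and longest stood there against 11.8% and 43.1%. In all, 6281 genes held a region, against 6569 with placement over gene windows and 4663 over whole chromosomes. Placement over gene windows puts every region in a window, while 1285 of the observed regions lay in other intergenic sequence. Its random counts and shares are therefore raised by construction, and values below them do not show a deficit. The median distance to the nearest protein-coding gene was 112 bp for target genes and 226 bp for the others (permutation p = 1e-05, 2-sided, the smallest possible). With each summit given to 1 gene only the medians were 194 and 189 bp (adjusted permutation p = 0.594). That assignment takes summits from genes with a close neighbour by construction, and counting a summit for each neighbour adds them. Neither comparison alone settles the difference. With gene bodies alone the medians were 118 and 199 bp (permutation p = 1e-05). For genes with a reproducible region the medians were 119 and 220 bp, a difference of −101 bp against −29.2 bp with random placement of the regions (permutation p = 0.002). Summits inside gene bodies alone left 3045 target genes, and summits at or above their list's median strength left 3203.

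Genes of photosynthesis, of rapid stress regulation, of light signalling and the clock, and of the gibberellin, brassinosteroid and auxin pathways carried summits far more often than length-matched genes. In the photosynthesis list 23 of 25 genes were targets where 5.69 were drawn on average, 4.04 times as many. Rapidly induced stress regulators counted 16 of 17 against 4.11, a ratio of 3.89, and light signalling and clock genes 18 of 21 against 6.19, a ratio of 2.91. Gibberellin and brassinosteroid genes counted 14 of 17 against 5.05, a ratio of 2.77 (permutation test, adjusted p = 0.00085 for each of these 4 lists). The auxin list counted 15 of 22 against 6.12 (ratio 2.45, adjusted permutation p = 0.00136), and the widely expressed reference genes 11 of 16 against 4.37 (ratio 2.52, adjusted permutation p = 0.00737). With summits at or above their list's median strength, the ratios were 8.30 for photosynthesis, 7.56 for stress regulators, 4.86 for light and clock genes, 4.23 for reference genes, 4.18 for auxin genes and 4.16 for gibberellin and brassinosteroid genes. With gene bodies alone, light signalling and clock genes fell to a ratio of 2.15 (adjusted permutation p = 0.212).

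**Figure D4:**
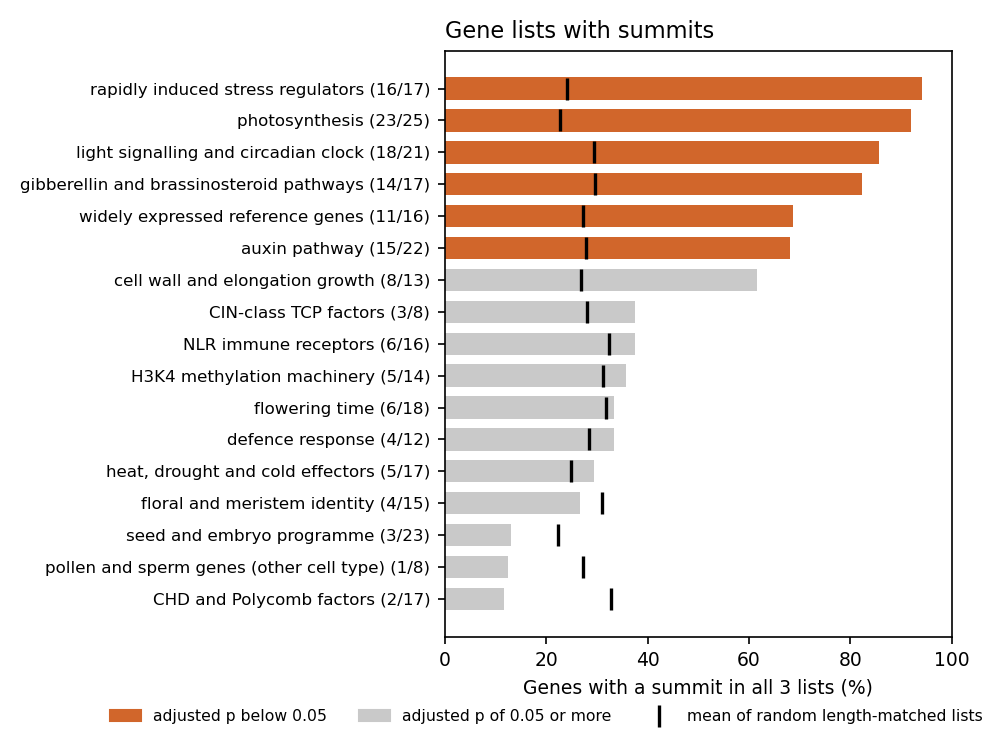
Share of genes in each of the 17 lists, in percent, with a summit in all 3 lists (bars, with counts in brackets), beside the mean of 10000 random length-matched lists (black ticks). Bars in orange mark the 6 lists with an adjusted p below 0.05, from 94.1% of stress regulators to 68.2% of auxin genes, and grey bars the others.

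Among photosynthesis genes, RBCS1A led, followed by RBCS1B at 60.6 ± 4.14 (SD, n = 3), the Rubisco activase gene RCA at 52.4 ± 6.45 and RBCS3B at 51.7 ± 2.27. RBCS1B and RBCS3B are genes for the Rubisco small subunit, and no reproducible region lay in the window of RCA. The summit of RBCS1B lay inside the gene at position 15383743 of chromosome 5. LHCA3, with a summit in 1 list, and PETE1, in 2 lists, were the members that were not targets. Among light and clock genes the pseudo-response regulator PRR9 was strongest, at 58.3, 47.1 and 56.4 in the 3 lists, 167 bp outside the gene at position 19232440 of chromosome 2. The phytochrome-interacting factor PIF5 (43.0 ± 11.7, SD, n = 3), the morning clock gene CCA1 (41.5 ± 9.61) and the photoreceptor gene PHYB (23.8 ± 1.17) followed. The CCA1 region lay 225 bp outside the gene, and CCA1 was not a target with each summit given to 1 gene. HYH, ELF3 and PHYA had summits in 2 lists.

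The stress regulators were led by the zinc finger gene CZF1 at 44.6 ± 10.2 (SD, n = 3), the calmodulin-like gene TCH2 at 38.1 ± 1.79, the cold-response activator CBF3 at 37.7 ± 3.72 and the jasmonate regulator MYC2 at 37.0 ± 1.61. MYB51, in 2 lists, was the remaining member. In the auxin list TIR1 was followed by the efflux carrier gene PIN7 at 49.8 ± 2.63 (SD, n = 3) and the conjugating enzyme genes GH3.3 and GH3.2 at 48.7 ± 6.99 and 29.9 ± 5.14. IAA14, IAA17, IAA29, ARF5 and TAA1 had no summit in any list. The brassinosteroid receptor gene BRI1 reached 26.1 ± 5.197 (SD, n = 3), the biosynthesis gene DWF4 22.5 ± 4.48, the transcription factor gene BES1 17.3 ± 2.13 and the DELLA gene GAI 16.3 ± 2.25. The gibberellin biosynthesis genes GA1 and GA20OX1 had none. Reference genes were led by UBQ10, UBQ11 (61.9 ± 10.6), ACT7 (46.3 ± 8.80) and GAPC2 (34.9 ± 3.21), and TIP41, HTA11 and HTA8 had no summit.

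Cell wall and elongation genes counted 8 of 13 against 3.50 drawn (ratio 2.28, adjusted permutation p = 0.0515). The cellulose synthase genes CESA1 (35.4 ± 7.44, SD, n = 3) and CESA6 (18.3 ± 6.79), the growth regulator PRE1 (31.4 ± 6.76) and the expansin gene EXPA1 (18.1 ± 4.49) were the strongest, and EXPA11, XTH17, XTH33 and PRE5 had no summit. Without replicate 2 the list passed the threshold, at an adjusted permutation p of 0.0204 and a ratio of 2.28. It also passed with Fisher's exact test without length matching, with stronger summits, with gene bodies alone and with each summit given to 1 gene. It did not with gene edges alone (ratio 1.62, adjusted permutation p = 0.656), with 1000 bp flanks (0.111), with summits in at least 2 lists (0.0704), without replicate 1 (0.0806) or without replicate 3 (0.0743).

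Neither genes of the H3K4 methylation machinery nor those of the CHD and Polycomb group differed from length-matched genes by enough to pass the threshold. Of 14 H3K4 machinery genes 5 were targets against 4.36 drawn (adjusted permutation p = 1). WDR5A itself (AT3G49660) had a summit in all 3 lists, 61 bp outside the gene at position 18415774 of chromosome 3, with 8.79 ± 3.45 (SD, n = 3). The methyltransferase gene ATX2 reached 8.90 ± 3.01, S2LB 7.27 ± 3.08 and ULT1 4.78 ± 1.87, and ASH2R, RBL, ATX1, ATX3 and ATXR3 had no summit. With each summit given to 1 gene, ATX2, S2LB and the remaining target S2LA were no longer targets. PKL (AT2G25170) had a summit in the lists of replicates 1 and 3, at 7.52 and 6.48, and not in that of replicate 2. Of the 17 CHD and Polycomb genes 2 were targets against 5.58 drawn (adjusted permutation p = 0.194), SWN at 9.93 ± 1.98 (SD, n = 3) and RING1A at 7.21 ± 1.69. SWN, with its region 142 bp outside the gene, was not a target with each summit given to 1 gene. PKR2, CHR5, MEA, FIE, VRN2, MSI1, LHP1, BMI1A, BMI1B and VAL1 had no summit in any list.

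For seed, flowering and floral genes no difference from length-matched genes passed the threshold. In the seed and embryo list 3 of 23 genes were targets against 5.16 drawn (adjusted permutation p = 0.757): ABI5 at 14.7 ± 5.53 (SD, n = 3), DOG1 at 12.04 ± 2.43 and WRI1 at 8.87 ± 3.24. The embryo regulators LEC1, NF-YB6, LEC2, FUS3, ABI3, ABI4, BBM and PHE1 and the storage and maturation genes CRA1, CRB, CRC, SESA1, SESA2, SESA3, SESA4, OLEO1, OLEO2, EM1 and EM6 had no summit. Among flowering time genes 6 of 18 were targets against 5.72 drawn (adjusted permutation p = 1), led by GI at 9.34 ± 5.91 (SD, n = 3), MAF3 at 8.46 ± 0.882, MAF2 at 5.65 ± 1.28 and CO at 5.36 ± 0.433. The GI region lay inside the neighbouring gene PFL, 147 bp outside GI. With each summit given to 1 gene, GI was not a target. FLC (AT5G10140), the repressor of flowering, had no summit in any list, nor had MAF4, MAF5, FT, TSF, SOC1, VIN3, FD and FLD. Of 15 floral and meristem identity genes 4 were targets against 4.66 drawn (adjusted permutation p = 1). They were the MADS-box genes AP3 (25.4 ± 8.65, SD, n = 3), SEP3 (24.6 ± 2.104), AP1 (20.3 ± 9.51) and FUL (5.33 ± 2.87), each with its strongest region outside the gene. LFY, AG, PI, STM, KNAT1, KNAT2, SEP1, SEP2, SHP1 and SHP2 had no summit.

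The TCP factors of the CINCINNATA class, growth regulators of the leaf, counted 3 of 8 against 2.24 drawn (adjusted permutation p = 1). TCP3 stood at 8.15 ± 1.96 (SD, n = 3), TCP24 at 7.46 ± 4.86 and TCP13 at 6.48 ± 2.23. TCP24 was not a target with each summit given to 1 gene. TCP10 and TCP2 had a summit in 1 list each, and TCP4, TCP5 and TCP17 in none. NLR immune receptor genes counted 6 of 16 against 5.18 drawn (adjusted permutation p = 1), with RPP4 at 13.2, 7.96 and 8.87 in the 3 lists, RPP13 at 9.63 ± 3.69 (SD, n = 3), ZAR1 at 5.07 ± 1.496 and RPS6 (AT5G46470) at 4.52 ± 0.825, and RPS4, RRS1, RPP5, RPP8 and LOV1 without a summit. Defence genes counted 4 of 12 against 3.41 drawn (adjusted permutation p = 1). FLS2, the flagellin receptor gene, stood at 11.2 ± 3.82 (SD, n = 3), WRKY33 at 9.19 ± 1.99, PAD4 at 7.98 ± 4.03 and BAK1 at 3.40 ± 1.097, while PR1, PR2, PR5, WRKY70 and FRK1 had no summit. Heat, drought and cold effectors counted 5 of 17 against 4.23 drawn (adjusted permutation p = 1), with COR47 at 23.9 ± 4.64 (SD, n = 3), P5CS1 at 15.0 ± 3.68, NCED3 at 13.8 ± 3.81 and HSP90.1 at 4.35 ± 1.07. HSP101, HSP22.0, HSP70-4, HSFA2, HSFA1A, RD29B, RD20, COR15A, KIN1 and RAB18 had no summit. HSP90.1 was not a target with each summit given to 1 gene. Of the 8 pollen and sperm genes, which mark a cell type other than seedling tissue, 1 was a target against 2.19 drawn (adjusted permutation p = 1). It was ACT11 at 13.0 ± 1.48 (SD, n = 3), and GEX2, HAP2, DUO1, HTR10, VGD1 and ACT4 had no summit.

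Among families gathered by gene symbol, ERF/AP2 factors, chlorophyll a/b-binding proteins, small auxin up RNAs, histones and ribosomal proteins lay above length-matched genes, and P450 enzymes and MADS-box factors below. Most of the chlorophyll a/b-binding target genes, CAB1, LHCB3 and LHCA1 among them, are also counted in the photosynthesis list, so the family is not a separate group. ERF/AP2 factors counted 20 of 30 against 5.89 drawn (18 of 27 against 5.09 without the translation release factor genes that share the symbol), chlorophyll a/b-binding proteins 17 of 21 against 4.78, small auxin up RNAs 28 of 80 against 10.5 and ribosomal proteins 32 of 66 against 16.8 (permutation test, adjusted p = 0.0006 for each). Histone genes counted 13 of 31 against 5.27 (adjusted permutation p = 0.00576), led by AT4G40040, AT4G40030 and AT5G10980, genes of histone H3.3, at 22.4 ± 4.01, 19.1 ± 0.634 and 14.7 ± 2.88 (SD, n = 3). The strongest region of AT4G40040 was that of AT4G40030, inside AT4G40030 and 100 bp outside AT4G40040. With each summit given to 1 gene, AT4G40040 was not a target. SAUR15 and its neighbour AT4G38840 shared a summit of 52.7 ± 12.6 (SD, n = 3). Other neighbours of that family shared summits too, such as AT2G21200 and AT2G21210 (37.0 ± 0.737) and SAUR28 and SAUR27 (17.4 ± 1.18). The random lists draw genes singly and do not keep neighbours together. Genes with SAUR as symbol stem counted 7 of 16 against 1.90 drawn. With each summit given to 1 gene they counted 2 against 1.26 (permutation p = 0.731). With summits at or above their list's median strength, the ratios were 6.32 for chlorophyll a/b-binding proteins and 4.52 for small auxin up RNAs. Cytochrome P450 genes counted 49 of 250 against 68.6 (ratio 0.714, adjusted permutation p = 0.0096), and MADS-box genes 13 of 98 against 21.9 (ratio 0.594, adjusted permutation p = 0.0449).

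Of the families, WRKY factors (20 of 71 against 18.8 drawn, adjusted permutation p = 0.841), heat shock proteins (14 of 36 against 10.1, 0.278, and 13 of 35 without HSPRO2, which is not a heat shock protein), receptor-like kinases (13 of 48 against 14.5, 0.841), F-box proteins (13 of 31 against 8.21, 0.140, and 0.0258 without replicate 2) and pentatricopeptide repeat proteins (4 of 12 against 3.25, 0.841) did not pass the threshold. The P450 and MADS-box deficits did not pass it with each summit given to 1 gene, at ratios of 0.806 and 0.764, and P450 genes stood at 1.02 with gene bodies alone. Neither deficit passed it with summits at or above their list's median strength. The MADS-box deficit also missed it with gene bodies alone, with gene edges alone and with 1000 bp flanks. Histones also lost the threshold with each summit given to 1 gene (ratio 1.89). Histones, ribosomal proteins and small auxin up RNAs lost it with gene bodies alone. Without length matching, small auxin up RNAs fell from a ratio of 2.67 to 1.41 (Fisher's exact test, adjusted p = 0.0653), and histones (1.69) and P450 genes (0.789) lost the threshold too.

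Adjacent genes were both targets more often than permuted genes. Of 27439 adjacent pairs 3196 were both targets, against a mean of 1707 after permutation within chromosome and length decile, a ratio of 1.87 (permutation p = 0.001, 1-sided, the smallest possible). In 2173 of these pairs the genes shared a summit in at least 1 list. With each summit given to 1 gene the count was 1139 against 874.2, a ratio of 1.303 (permutation p = 0.001). With gene bodies alone it was 472 against 343.0, a ratio of 1.376 (permutation p = 0.001). With pairs that shared a summit left out, 1023 pairs remained against 1389, a ratio of 0.737 (permutation p = 1). This adjacency is along the chromosome and carries no measurement of contacts in the nucleus.

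Regions ranged from 51.4 per Mb on chromosome 2 to 58.4 per Mb on chromosome 1, and the 5 chromosomes were not tested against each other. They were scarce in the gene-poorest 3 Mb of each chromosome. These windows held 79 regions where random placement gave 836.6, a ratio of 0.0944 (permutation p = 0.002, 2-sided, the smallest possible), or 5.27 per Mb against 63.4 elsewhere. The windows were chosen for few protein-coding genes, and regions gathered at gene edges. A deficit against placement over the whole chromosome therefore follows in part from that choice. Of the 682 protein-coding genes in them 64 (9.38%) were targets, against 25.2% of the other genes (Fisher's exact test, 2-sided, p = 4.02e-25, over genes, which are not independent).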

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

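No paired analysis was possible because the IP and input libraries share replicate numbers but summit lists of the input libraries were not analysed here. Depth is unknown, so its effect on the weak summits, most of which were not shared by all 3 lists, could not be set apart. Random placement of features in gene windows and of regions for gene properties, gene-body assignment of lists and properties, assignment of each summit to 1 gene, the wider windows for lists, the other linking distances and the narrower family definitions were chosen after the data were seen. Of the alternative values, 362 kept their side of the threshold or moved little, 15 lost the threshold and 9 gained it. A further 7, of results past the threshold, turned direction. The other 6 were counts or coefficients that moved by more than 1.5 times or past the SD of the pairs of lists. Results past the threshold in neither setting count as kept even where the direction turned. With gene bodies alone, for example, H3K4 machinery genes went from a ratio of 1.15 to 0.529. The cause was not tested where none is given. Keeping summits at or above the list's median strength, which removes summits by construction, gave 3267 shared regions, 3203 target genes, 24.1% other intergenic sequence (above random), cell wall genes at 3.52 and F-box proteins at 2.52 times length-matched genes (both past the threshold), and MADS-box and P450 genes at 0.589 and 0.984, neither past it. Gene bodies alone gave 3045 target genes and 2 families past the threshold. There, light and clock genes stood at 2.15, ribosomal proteins at 1.47, histones at 1.32, small auxin up RNAs at 1.67, MADS-box genes at 0.309 (none past it), P450 genes at 1.02 (turned) and cell wall genes at 3.87 (past it). With each summit given to 1 gene, cell wall genes (2.88) and F-box proteins (2.22) passed, histones (1.89), MADS-box (0.764) and P450 genes (0.806) did not, and the difference in distance to the nearest gene turned to 5 bp. That assignment takes summits from genes with a close neighbour by construction. Without length matching, Fisher's exact test left 4 families, with cell wall genes at 2.48 (past) and histones, small auxin up RNAs and P450 genes at 1.69, 1.41 and 0.789 (not past). MADS-box genes also missed it with 1000 bp flanks (0.645) and with gene edges alone (0.604), and F-box proteins passed with summits in 2 lists or more (1.64). Random placement of the regions, added because window size grows with gene length, turned the length difference to −135.4 bp against random, or −143.7 bp in gene windows. Random placement in gene windows left nearly no pseudogene sequence by construction (0.318%), so the pseudogene ratio of 1.22 (0.389% of regions) there does not bear on the deficit, and leaving out pairs that share a summit turned the adjacency ratio to 0.737, a selection that removes pairs of target genes by construction. For the Spearman coefficients, leaving out a replicate only kept the value of the other pair over the same regions. The resulting 0.740 to 0.760 restates the main values and is no separate check, though counted among the alternative values. Leaving out each replicate gave cell wall ratios of 2.06 to 2.28 and F-box ratios of 1.44 to 1.74. Of the replicates, only leaving out replicate 2 took both groups past the threshold, at adjusted permutation p of 0.0204 and 0.0258. Not run were reciprocal overlap and the share of a peak inside a window, which need widths, the choice between summit and midpoint, and the motif alternatives, which need sequence.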

Other observations

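The search over symbol stems and the test of the flank were chosen after the results they concern were seen, and the counts over RNA gene classes after the gene lists were tested but before those counts were seen. Among 170 families sharing a symbol stem and holding at least 10 genes, 4 lay above length-matched genes and 1 below. A stem can join unrelated genes. Genes of the ERF stem, which joins ethylene response and translation release factors, counted 18 of 25 against 4.99 drawn (adjusted permutation p = 0.0113), genes of the ERD stem, most named for early response to dehydration, 11 of 13 against 3.63 (0.0113), arabinogalactan protein genes (AGP) 12 of 30 against 4.25 (0.0255) and B-box zinc finger genes (BBX) 12 of 20 against 4.66 (0.0340). CYP genes lay below, at 37 of 229 against 62.4 (adjusted permutation p = 0.0113). BBX29 (35.7 ± 7.20, SD, n = 3), BBX28 (27.9 ± 15.0) and BBX19 (24.8 ± 3.58) led the B-box genes, ERD14 (35.2 ± 8.20) followed ERD15, and AGP15 (52.9 ± 5.01) led the AGP genes. With each summit given to 1 gene, the ERF, ERD and BBX stems stayed past the threshold and AGP and CYP did not (adjusted permutation p = 0.219 for each), although their ratios moved little, from 2.82 to 2.74 and from 0.593 to 0.666. The PUB stem passed only there, at 12 of 22 against 4.42 (adjusted permutation p = 0.0340). BBX19 was not a target there.

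RNA genes outside the protein-coding set also lay near regions. These counts use 500 bp flanks, and a region of a neighbouring protein-coding gene counts too. The region near the tRNA gene AT4G31695, for example, is also that of the ribosomal protein gene RPS6 (AT4G31700), 127 bp outside RPS6. Regions were not assigned to 1 gene here. Of 625 tRNA genes 224 (35.8%) lay within 500 bp of a reproducible region, against 37.2 with regions placed at random in gene windows. The counts were 43 of 287 snoRNA genes against 15.2, 15 of 82 snRNA genes against 6.04 and 507 of 3480 lncRNA genes against 248 (adjusted permutation p = 0.0032 for tRNA, snoRNA and lncRNA genes and 0.00533 for snRNA genes). With regions placed over whole chromosomes the ratios were 6.15 for tRNA, 2.501 for snoRNA, 2.78 for snRNA and 1.77 for lncRNA genes, each past the threshold. Other ncRNA genes counted 32 of 221, at ratios of 2.503 in gene windows (adjusted permutation p = 0.0032) and 1.36 over chromosomes (0.121). Of 326 microRNA genes 26 lay near a region, against 14.4 (adjusted permutation p = 0.0114), but with regions placed over whole chromosomes against 20.9 (permutation p = 0.358). Examples, taken after their values were seen, were microRNA genes, of which MIR167a had a mean −log10 q of 26.2, MIR163 19.3, MIR166a 16.5 and MIR159a 15.3, and the trans-acting siRNA gene TAS3 had 22.1. The region lay outside the gene in each of these examples. The summit of TPR3 lay inside the lncRNA gene AT5G04345. There were 885 regions more than 1000 bp from any protein-coding gene. The strongest of them, at position 525379 of chromosome 4, lay 1130 bp from a gene edge between WRKY22 and AT4G01245 with 95.2 ± 5.30 (SD, n = 3). A region at position 18822080 of chromosome 3, with 66.5 ± 10.4 (SD, n = 3), lay 4080 bp from a gene edge, between DWF4 and U1-70K.

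The groups with an excess of summits include photosynthesis and widely expressed reference genes, and transcription was not measured here. A hypothesis is that summits gather at strongly transcribed or open loci whatever the bait, and tRNA genes, which RNA polymerase III transcribes, lay near regions 6.02 times as often as with random placement in gene windows, as that hypothesis predicts. The region near a tRNA gene can be that of a neighbouring protein-coding gene, which these counts do not separate. Counting of a neighbour's summit through the flank was tested too. With each summit given to 1 gene, 10 of 11 groups with an excess (90.9%), some of which share genes, stayed past the threshold. That assignment still counts flank summits for the nearest gene. With gene bodies alone, light and clock genes lost the threshold (adjusted permutation p = 0.212). So did ribosomal proteins (0.490), histones (0.998) and small auxin up RNAs (0.490). For these groups the flank stays open. A biological explanation through WDR5A was not tested, since no untagged line or second genotype was analysed here. It may hold together with the hypothesis of transcribed or open loci.

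The excess of adjacent target genes was tested against the idea that a single summit is counted for both neighbours. With each summit given to 1 gene the ratio fell from 1.87 to 1.303 and stayed above 1 (permutation p = 0.001). Shared summits thus account for part of the excess. With gene bodies alone the ratio was 1.376 (permutation p = 0.001). In both settings a summit inside overlapping genes still counted for each of them. Whether shared summits account for the whole excess therefore stays open. Clustering of genes with similar transcription, or an effect of PKL, may underlie any rest, and neither was tested.

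The gathering of regions at gene edges could come from summit and gene coordinates that are offset by a difference of build. In 100% of the 26 blocks of 5 Mb the share within 250 bp of an edge was highest with no shift. Over all regions it was 52.0% against 21.1% and 21.8% at shifts of 500 bp to either side. This argues against an offset of 500 bp or more, and shifts under 500 bp were not tried. Whether the regions mark gene starts or gene ends stays open, since strand was not used here.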
